A study of Homo sapiens with 14 samples.

How the data were processed

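The data were gene-level RNA-seq counts of cultured human cells, the gastric cancer line NUGC4 and the liver cancer line HepG2, from 14 samples in 6 groups. The values are whole-number read counts per gene symbol, deposited by the authors as 1 table of 59250 gene symbols and 14 columns of values. Per the labels' protocols, messenger RNA was captured by its poly(A) tail, the libraries were sequenced as read pairs, the knockout cells came from single-cell clones, and HepG2 received a tagged CTNNB1 without its degradation signal by lentivirus. Per the submitters' processing notes, reads were aligned with STAR 2.7.10a and the build was hg38. The counting tool, the gene annotation and the strand setting are not given in the sources used here, and neither is how reads shared between genes were treated, so genes with near-identical copies, overlapping genes and antisense genes are uncertain. In all 57841 of the symbols occurred in an NCBI RefSeq gene table (assembly GRCh38.p14), which gave gene positions and biotypes.

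Columns were matched to samples by name alone. Of the 14 columns 13 were matched, and 1 column whose name fits no sample's labels was used in no step. The design was written for all 10 NUGC4 libraries; the fits hold the 9 that were matched, namely 4 wild-type, 2 knockout, 1 vector and 2 sgRNA1 libraries. Total counts per library were 9167761 to 17668394 in NUGC4 and 13138681 to 23914120 in HepG2. At these depths 3 counts over the libraries of a group served as the floor for a gene with no counts there, and ratios on 1 to 3 counts carry a 95% exact counting interval.

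Counts were tested in R 4.3.3 with the quasi-likelihood test of edgeR 4.0.16, with TMM factors, the filter filterByExpr and Benjamini-Hochberg adjustment, at an adjusted p under 0.05. The 9 NUGC4 libraries entered 1 fit with a mean per group (5 residual degrees of freedom) and the 4 HepG2 libraries another (2). The comparisons were knockout against wild type, CRISPRi against vector and CTNNB1 overexpression against vector, with the difference between the first 2 effects, the vector against wild type, and the overlap of knockout and CRISPRi calls by a hypergeometric test. Standard errors are of the log2 fold change. CPM of ARID1A, ZNF10, ZIM3, ARID1B and CTNNB1 are scaled to the total count of the library, and other CPM use TMM-adjusted library sizes.

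Before the data were examined, 41 gene lists with 1431 entries were fixed, of which 1429 were matched, 15 of them through an older or newer symbol. Lists with at least 5 members tested were compared with all other genes by camera in limma 3.58.1, on log2 CPM with a prior count of 2, voom weights and a preset inter-gene correlation of 0.01. The test was repeated with an estimated correlation and with fry. Members called were counted over all genes and adjusted over the list alone. Lists of markers of other cell types were too thinly expressed in NUGC4 to test.

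The rule for named genes, also fixed before the data were examined, took the targeted gene and the 10 largest rises and 10 largest falls per main comparison among genes past the threshold. It asked for a mean of at least 5 CPM in the higher group, no overlap between the groups' libraries, and a symbol that is no clone, locus or pseudogene name. It added up to 4 members with the smallest adjusted p of each list that passed or that bears on the question, 5 genes per direction for the second contrasts, and 8 for the overlap. How the rule reads a symbol that ends in P and digits was settled after first top lists had been seen: such a symbol was passed over only if its RefSeq biotype is not protein-coding. The text names part of the rule's genes, a choice made after their values were seen, and some of them are not reported here. AXIN2, ATF4, HSPA5 and MANF in HepG2, TRIM25 in the knockout and SAMD9 under CRISPRi lie outside the rule.

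ARID1A in the library labelled knockout replicate 2 goes against its label, so values without it, planned as 1 of the settings that leave out a library, are given beside those with the group as named. The weight put on them was decided after first fits had been seen. That fit holds 8 libraries and has 4 residual degrees of freedom, and its knockout group is 1 library. The vector group is 1 library in every fit, and single libraries are assumed to vary like the groups with replicates. The other alternatives, set before the data were examined, were DESeq2 size factors, no filter on low counts, the Wald test of DESeq2 1.42.0, limma-voom, an absolute log2 fold change of at least 1, the replicate number as a block, only the compared groups in the fit or all mapped libraries in 1 fit, and leaving out each library in turn. Knockout and vector calls share the wild-type libraries, so their overlap was also computed for independent lists, for 10 simulated sets of unchanged groups and for the 6 ways of giving 2 wild-type libraries to each comparison, all chosen after seeing the data. Protein-coding genes alone, the block with all NUGC4 libraries in the fit, and the overlap without the doubted library, were chosen after seeing the data.

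The steps were tested on simulated data with 100 genes changed by a log2 of 1 and 100 by a log2 of 2 per comparison. Of the latter, edgeR called 95 in the knockout as named (18148 genes), 100 without the doubted library (17858), 73 for CRISPRi as named (18133), 100 without that library (17824) and 100 in HepG2 (15425). False calls made up 2.94% of the simulated calls in the knockout as named and 6.40% without the doubted library. They made up 7.14% for CRISPRi as named, 6.90% without that library and 5.21% in HepG2. The changed genes were drawn from those with a mean of at least 5 CPM, and every library was simulated with the fitted spread. Recovery in groups of 1 library thus rests on the assumption that they vary like the groups with replicates. Transposable elements, which the design provided for, were not analysed here because the table's rows are genes.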

Results

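RNA that the labels describe as poly(A)-captured was sequenced from a pair of human cancer cell lines, the gastric cancer line NUGC4 and the liver cancer line HepG2. Gene-level counts of 13 libraries were compared. In NUGC4 the groups were unmodified cells (wild type, 4 libraries), single-cell clones with a knockout of ARID1A (2 libraries by name, 1 of which goes against its label), cells with CRISPR interference (CRISPRi) against ARID1A through 1 guide RNA (sgRNA1, 2 libraries) and the vector control of the CRISPRi cells (1 library was matched to this group by name). ARID1A encodes a subunit of the BAF chromatin remodelling complex. In HepG2 the groups were vector control cells (2 libraries) and cells carrying a lentiviral CTNNB1 that lacks the exon holding the degradation signal of beta-catenin (2 libraries). Counts per library ran from 9167761 to 17668394 in NUGC4 and from 13138681 to 23914120 in HepG2. The labels do not say whether libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries. Transposable elements, which the series title names, were not analysed here, since the rows used are genes.

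ARID1A (chromosome 1, 26696015 to 26782104, GRCh38.p14) stood at 128.03, 136.61, 117.48 and 117.96 CPM (counts scaled to the library's total) in the wild-type libraries, a mean of 125 ± 9.13 (SD, n = 4). Knockout replicate 1 held 34.3 CPM, whereas the library labelled knockout replicate 2 held 140.59 CPM, close to the 139.77 CPM of the vector control. The sgRNA1 libraries held 57.6 and 53.5 CPM. A pair of transcripts that wild-type cells nearly lacked also separated the libraries. ZIM3, a KRAB zinc finger gene whose repressor domain is used in CRISPRi constructs, reached 26.1 and 28.2 CPM in the sgRNA1 libraries and at most 0.06 CPM in every other NUGC4 library. ZNF10, the source of another KRAB domain used in such constructs, stood at 23.39 CPM in the vector library and 19.9 CPM in the library labelled knockout replicate 2, against at most 0.21 CPM elsewhere in NUGC4. Across expressed genes the library labelled knockout replicate 2 and the vector library gave a chi-square per degree of freedom of 2.46, against 247.22 for the same library and knockout replicate 1. ARID1A and these constructs therefore go against the label of that library, and the counts of genes and the lists of the knockout are given with the group as named and again without it.

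**Figure D1:**
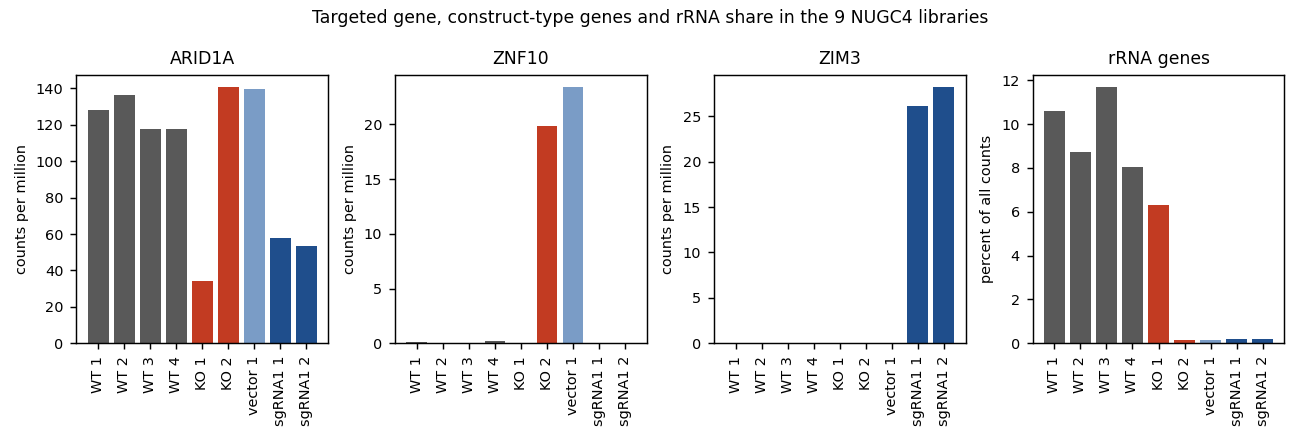
Bars show CPM of ARID1A, ZNF10 and ZIM3 and the share of counts on ribosomal RNA (percent) in each of the 9 NUGC4 libraries. ARID1A was at 34.3 CPM in knockout replicate 1 but 140.59 CPM in the library labelled knockout replicate 2, and ribosomal RNA was above 6% only in the wild-type libraries and knockout replicate 1.

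The NUGC4 libraries also fell into 2 kinds by RNA content. Ribosomal RNA took 8.04 to 11.7% of counts in wild type and 6.30% in knockout replicate 1, but 0.161 to 0.176% in the library labelled knockout replicate 2, the vector and the sgRNA1 libraries. Replication-dependent histone transcripts, which lack a poly(A) tail, took 0.185 to 0.229% against 0.0107 to 0.0122%, and mitochondrially encoded genes took 0.830 to 2.49% against 7.94 to 8.21%. Knockout replicate 1 is thus compared with wild type within 1 kind of library, and CRISPRi with its vector within the other. The library labelled knockout replicate 2 is of the other kind from its wild-type controls.

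In knockout replicate 1 the matrix genes FN1 and SPOCK3, the interferon-induced genes OAS2 and IFI6 and the MHC class I gene HLA-B stood above wild type. FN1, which encodes the matrix protein fibronectin, was at 520.26 CPM in knockout replicate 1 and 1.56 ± 0.42 CPM in wild type (SD, n = 4). SPOCK3, a matrix proteoglycan gene, had no counts in wild type and was at least 570.5-fold higher in knockout replicate 1 (floor of 3 counts over the group). OAS2, an interferon-induced sensor of double-stranded RNA, was at 84.8 CPM against 4.20 ± 0.72, and IFI6, another interferon-induced gene, at 173.73 against 10.99 ± 1.90 (SD, n = 4). HLA-B was at 372.67 against 107.11 ± 9.52 CPM. These genes also passed the test with the group as named, where FN1 gave a log2 fold change of 7.44 ± 0.94 (SE; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0026), OAS2 of 3.50 ± 0.59 and HLA-B of 1.38 ± 0.23. Without knockout replicate 1 only the library that keeps ARID1A stands for the knockout. There SPOCK3 stood at 5.08, a value that depends on the prior count because wild type had no counts of it. FN1 stood at 4.04, IFI6 at 2.17, OAS2 at 1.42 and HLA-B at 0.77 there. Passing as named therefore does not tie these rises to lower ARID1A. The as-named call of SPOCK3 was lost without any single wild-type or sgRNA1 library, with adjusted p in edgeR from 0.0621 to 0.0682. Of 24 mesenchymal and matrix genes 10 rose and none fell as named, the same counts adjusted over the list alone (camera, adjusted p = 0.0146, and adjusted p = 0.109 with an estimated correlation). With the library labelled knockout replicate 2 left out, 11 of 23 rose and 2 fell, again the same counts adjusted over the list alone (camera, adjusted p = 0.0013, and adjusted p = 0.124 with an estimated correlation). The vector against wild type gave 11 and 1 in that fit.

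As named, 2576 of 19124 genes rose and 1870 fell in the knockout (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). Without the library labelled knockout replicate 2, 3682 rose and 3546 fell of 18913 tested, with the single remaining knockout library assumed to vary like the other groups. With protein-coding genes alone that fit gave 2928 and 2746. Of 4443 as-named calls tested in both fits, 3695 (83.2%) were called in the same direction in the vector against wild type in the fit without that library, 3725 (83.8%) in knockout replicate 1 against wild type, and 3055 (68.8%) in both. Knockout replicate 1 is itself part of the as-named group and has the same wild-type controls. Its share of 83.8% is thus raised by construction and is no replication of the as-named calls. For the vector, independent lists would share 604.64 higher and 386.58 lower genes. In 10 simulated sets of unchanged groups at most 1 gene was shared, but at most 2 genes were called higher and 1 lower in the knockout, too few to give a share. With the 4 wild-type libraries split between the comparisons, the knockout calls fell to 353 to 783 higher and 345 to 684 lower over the 6 splits, and 675 to 1333 of them were shared with the vector (90.9 to 96.7%). ARID1A itself changed by −0.40 ± 0.42 as named (edgeR, adjusted p = 0.497) and fell by 1.74 ± 0.14 without that library (edgeR, adjusted p = 1.5e-08; the alternatives ran from 1.5e-08 to 0.610). Genes that moved alike in both fits included CYP17A1, a steroid hydroxylase gene, which rose by 4.53 ± 0.47 as named. MAML2, a Notch coactivator gene, fell by 3.31 ± 0.31, PELI1, a ubiquitin ligase gene, by 2.699 ± 0.27, and AVIL, an actin regulator gene, by 2.87 ± 0.22. Without knockout replicate 1 only the library that keeps ARID1A stands for the knockout. There CYP17A1 stood at 3.73, MAML2 at −3.42, PELI1 at −2.40 and AVIL at −2.81, so agreement of the fits does not tie these changes to lower ARID1A. PHLDB2 rose by 5.99 ± 1.20 and PIK3C2G fell by 2.35 ± 0.53, where PHLDB2 stood at 0.80 without knockout replicate 1 (edgeR, adjusted p = 0.207). PIK3C2G stood at −3.95 without the doubted library and −1.63 without knockout replicate 1, and passed in both. CLEC4E, an innate immune receptor gene, had 1 count in the wild-type libraries, and its ratio without the doubted library was 502 (95% counting interval 88.8 to 19948). The glutamate receptor gene GRM5 gave a ratio of 2013.9 (360.14 to 79671) and the branched-chain transaminase gene BCAT1 1154.9 (206 to 45744), again on 1 wild-type count. As named, CLEC4E lost its call without wild-type replicate 2 or knockout replicate 1 (edgeR, adjusted p of 0.0585 and 0.0620), GRM5 without wild-type replicate 1 or 2 or knockout replicate 1 (0.0518, 0.0807 and 0.553) and BCAT1 without any single wild-type library (0.0507 to 0.0840). Such intervals and floors cover counting error only. Losses that did not pass as named but did without that library were MYBPC1, at least 1507.3-fold lower in knockout replicate 1 than its 322.67 ± 20.3 CPM in wild type, MLPH (−4.52 ± 0.17) and FAM189A2 (−4.99 ± 0.21); MYBPC1 stood at 279.72 CPM in the library labelled knockout replicate 2. MLPH (−0.51) and FAM189A2 (−1.01) also passed without knockout replicate 1. Of the 36 genes named for this comparison besides ARID1A, 29 passed as named and all 36 without that library, the largest adjusted p then being 0.026 in edgeR, where the alternatives ran from 1.6e-29 to 0.957.

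Interferon response, MHC class I, chemokine, checkpoint ligand and nucleic acid sensing genes were higher as lists in the knockout, while MHC class II genes did not pass. As named, 2 of 7 MHC class II genes rose and none fell (3 and 0 adjusted over the list alone; camera, adjusted p = 0.130). With the doubted library left out, 2 of 6 rose and none fell, the same counts adjusted over the list alone (camera, adjusted p = 0.479). As named, 32 of 52 type I interferon response genes rose and none fell (37 and 0 adjusted over the list alone), with a median log2 fold change of 1.10 (camera, adjusted p = 2.3e-09, and adjusted p = 0.337 with an estimated correlation). Without the library labelled knockout replicate 2, 47 rose and 1 fell (48 and 1 adjusted over the list alone), with a median of 1.54 (camera, adjusted p = 1.4e-21, and adjusted p = 0.010 with an estimated correlation). OASL, an OAS family gene, rose by 4.86 ± 0.24 in that fit, and the member that fell, TRIM25 (−0.33 ± 0.11), a ubiquitin ligase gene of the RIG-I pathway, was named after its values were seen. Of 28 MHC class I antigen presentation genes 17 rose and none fell as named (20 and 0 adjusted over the list alone; camera, adjusted p = 8.1e-10, and adjusted p = 0.032 with an estimated correlation). TAP1, which carries peptides into the endoplasmic reticulum, was among them at 1.20 ± 0.35 as named and 1.81 ± 0.13 without the library labelled knockout replicate 2. Without the doubted library 21 rose and none fell (22 and 2 adjusted over the list alone; camera, adjusted p = 1.4e-10, and adjusted p = 0.052 with an estimated correlation). Chemokine and cytokine genes gave 16 higher and 1 lower of 28 as named (17 and 3 adjusted over the list alone; camera, adjusted p = 2.8e-05, and adjusted p = 0.032 with an estimated correlation), with LIF at 1.70 ± 0.12 and IL32 at 1.48 ± 0.16. Without the doubted library they gave 18 and 3 (19 and 3 adjusted over the list alone; camera, adjusted p = 5.6e-06, and adjusted p = 0.0418 with an estimated correlation). Immune checkpoint ligand genes gave 11 higher and 1 lower of 29 as named (13 and 2 adjusted over the list alone; camera, adjusted p = 0.0014, and adjusted p = 0.0495 with an estimated correlation), among them the TIGIT ligand gene NECTIN2 at 1.22 ± 0.22 (1.63 ± 0.11 without the doubted library) and NT5E, which encodes an adenosine-producing ectoenzyme, at 1.60 ± 0.44. NT5E stood at 2.29 ± 0.16 without the doubted library. The as-named calls of TAP1 and NT5E were lost without knockout replicate 1 (0.15 and 0.20) and without any single wild-type or sgRNA1 library. OASL stood at 2.02, IL32 at 1.23 and NECTIN2 at 0.63 without knockout replicate 1. LIF stayed between 1.66 and 1.78 over the libraries left out. OASL, IL32, NECTIN2 and LIF thus also stood above wild type in the library that keeps ARID1A. The checkpoint list gave 15 and 4 without the doubted library (17 and 5 adjusted over the list alone; camera, adjusted p = 0.0029, and adjusted p = 0.0832 with an estimated correlation). Nucleic acid sensing genes gave 8 higher and none lower of 27 as named (10 and 2 adjusted over the list alone; camera, adjusted p = 0.0059, and adjusted p = 0.095 with an estimated correlation). With that library left out they gave 15 and 2 (15 and 3 adjusted over the list alone; camera, adjusted p = 0.00027, and adjusted p = 0.0847 with an estimated correlation). Without the doubted library in the fit, the interferon list was also higher in the vector than in wild type, with 23 higher and 3 lower, the same counts adjusted over the list alone, and a median of 0.42 (camera, adjusted p = 0.0022, and adjusted p = 0.082 with an estimated correlation). The vector shares its kind of library with the library labelled knockout replicate 2. In the same fit MHC class I genes gave 19 and none in the vector against wild type, the same counts adjusted over the list alone (camera, adjusted p = 2.1e-06, and adjusted p = 0.082 with an estimated correlation). Chemokine and cytokine genes gave 14 and 2 (15 and 2 adjusted over the list alone; camera, adjusted p = 0.00063, and adjusted p = 0.082 with an estimated correlation). Checkpoint ligand genes gave 11 and 2, the same counts adjusted over the list alone (camera, adjusted p = 0.0064, and adjusted p = 0.082 with an estimated correlation).

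**Figure D2:**
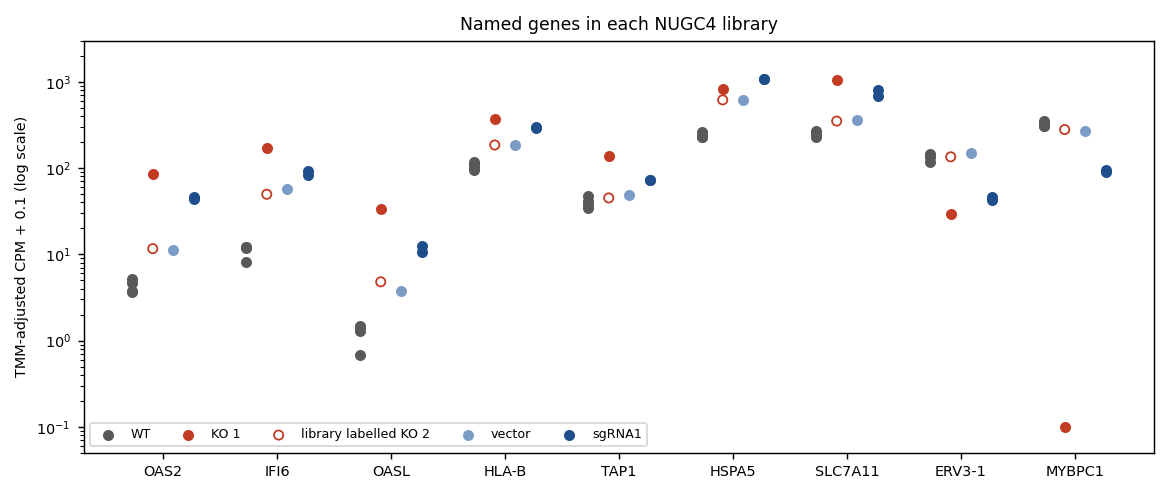
Each point is 1 NUGC4 library, with TMM-adjusted CPM plus 0.1 on a log axis for 9 genes. OAS2 was at 84.8 CPM in knockout replicate 1 against a wild-type mean of 4.20, and MYBPC1 had no counts in knockout replicate 1 alone.

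Stress response, NF-kB, NRF2 and epithelial lists were also higher in the knockout. AP-1 and immediate early genes, which fell under CRISPRi, gave 27 higher and none lower of 35 as named (31 and 1 adjusted over the list alone). For that list camera gave adjusted p = 1.4e-09, and adjusted p = 0.288 with an estimated correlation. The vector, of the same kind of library as the library labelled knockout replicate 2, also stood above wild type in this list. Its as-named rise is thus not tied to lower ARID1A. Unfolded protein response and integrated stress response genes gave 24 higher and none lower of 36 as named (25 and 0 adjusted over the list alone; camera, adjusted p = 7.0e-10, and adjusted p = 0.032 with an estimated correlation). HSPA5, the main chaperone of the endoplasmic reticulum, rose by 1.57 ± 0.14 and DNAJB9, a co-chaperone gene, by 1.47 ± 0.39. HSPA5 stood at 1.33 without knockout replicate 1, on the library that keeps ARID1A. DNAJB9 stood at 2.12 ± 0.14 without the library labelled knockout replicate 2, and its as-named call was lost without knockout replicate 1 (0.26) and without any single wild-type or sgRNA1 library. With the library labelled knockout replicate 2 left out, 30 rose and 1 fell, the same counts adjusted over the list alone (camera, adjusted p = 8.4e-13, and adjusted p = 0.0418 with an estimated correlation). NF-kB targets gave 13 higher and none lower of 24 as named (16 and 0 adjusted over the list alone; camera, adjusted p = 4.8e-07, and adjusted p = 0.032 with an estimated correlation). The same list gave 16 and 1 without that library (18 and 1 adjusted over the list alone; camera, adjusted p = 4.3e-07, and adjusted p = 0.0418 with an estimated correlation). NRF2 and glutathione genes gave 21 and none of 33 as named, with a median of 0.80 (26 and 0 adjusted over the list alone; camera, adjusted p = 1.2e-11, and adjusted p = 0.163 with an estimated correlation). Without that library they gave 21 and 1, the same counts adjusted over the list alone, with a median of 0.48 (camera, adjusted p = 6.8e-07, and adjusted p = 0.0418 with an estimated correlation). As named, SLC7A11, the cystine transporter gene, rose by 1.48 ± 0.33 and AKR1C1, an aldo-keto reductase gene, by 1.28 ± 0.11. Without knockout replicate 1 SLC7A11 stood at 0.47 and AKR1C1 at 1.22. SLC7A11 lost its call without wild-type replicate 2 (edgeR, adjusted p = 0.0507). Epithelial junction and keratin genes gave 17 higher and 3 lower of 36 as named (20 and 3 adjusted over the list alone; camera, adjusted p = 3.3e-05, and adjusted p = 0.032 with an estimated correlation). With that library left out they gave 25 and 7 (26 and 7 adjusted over the list alone; camera, adjusted p = 3.4e-05, and adjusted p = 0.0418 with an estimated correlation). In the latter fit the vector also stood above wild type in these lists. NRF2 and glutathione genes gave 30 higher and none lower there, with a median of 0.78 (32 and 0 adjusted over the list alone; camera, adjusted p = 7.5e-16, and adjusted p = 0.035 with an estimated correlation). Stress response genes gave 21 and 3 (23 and 5 adjusted over the list alone; camera, adjusted p = 2.1e-06, and adjusted p = 0.082 with an estimated correlation). NF-kB targets gave 15 and none, the same counts adjusted over the list alone (camera, adjusted p = 2.1e-05, and adjusted p = 0.072 with an estimated correlation). Epithelial genes gave 16 and 4 (16 and 5 adjusted over the list alone; camera, adjusted p = 0.0064, and adjusted p = 0.082 with an estimated correlation). Proliferation genes differed between the fits. As named, 3 of 42 replication and S phase genes rose and 3 fell (3 and 3 adjusted over the list alone), while without the library labelled knockout replicate 2 there were 3 and 21 (3 and 22 adjusted over the list alone; camera, adjusted p = 0.00035, and adjusted p = 0.052 with an estimated correlation). TK1, a thymidine kinase gene, was at 0.08 ± 0.34 as named and −0.95 ± 0.13 without that library, and ASPM, a spindle gene, at −0.85 ± 0.25 and −1.40 ± 0.16. The as-named call of ASPM was lost without any single wild-type or sgRNA1 library. Mitosis genes went from 2 higher and 1 lower of 40 to 1 and 17 (0 and 0, then 1 and 18, adjusted over the list alone; camera without that library, adjusted p = 0.00013, and adjusted p = 0.336 with an estimated correlation). Under CRISPRi as named, mitosis and replication genes had medians of 0.21 and 0.11, opposite in sign to knockout replicate 1, though no gene passed there. The mitosis list passed camera upward there with the preset correlation but not with an estimated one, and the replication list did not pass. The vector also moved the other way in the fit without the library labelled knockout replicate 2. Replication genes gave 29 higher and 2 lower in the vector against wild type (29 and 3 adjusted over the list alone; camera, adjusted p = 2.4e-05, and adjusted p = 0.072 with an estimated correlation) and mitosis genes 24 and none (25 and 0 adjusted over the list alone; camera, adjusted p = 2.4e-05, and adjusted p = 0.282 with an estimated correlation).

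Genes that silence transposable elements did not pass camera in the knockout. As named 7 of 40 rose and 2 fell (7 and 2 adjusted over the list alone; camera, adjusted p = 0.517), and without the library labelled knockout replicate 2 there were 7 and 7, the same counts adjusted over the list alone (camera, adjusted p = 0.935). Among those that rose were APOBEC3B (1.35 ± 0.18), a cytidine deaminase gene of the family that restricts retroelements, and SAMHD1 (0.78 ± 0.22), which encodes a nucleotide hydrolase. APOBEC3B stood at 1.13 without knockout replicate 1. SAMHD1 stood at 1.16 ± 0.13 without the library labelled knockout replicate 2, and its as-named call was lost without knockout replicate 1 (0.24) and without any single wild-type or sgRNA1 library. Of 27 ERV-derived and domesticated element genes 5 rose and 3 fell as named, the same counts adjusted over the list alone (camera, adjusted p = 0.981), against 3 and 8 without that library (3 and 9 adjusted over the list alone; camera, adjusted p = 0.218). ERV3-1, the envelope gene of an endogenous retrovirus, was at 29.3 CPM in knockout replicate 1 against 135.8 ± 12.1 in wild type (SD, n = 4), a log2 fold change of −2.21 ± 0.15 without that library and −0.72 ± 0.46 as named; it overlaps a zinc finger gene, so its counts are uncertain. PEG10, a domesticated retrotransposon gene, stood at −2.59 ± 0.34 without that library and −0.81 ± 0.53 as named. Polycomb genes gave 5 higher and 2 lower of 28 as named, the same counts adjusted over the list alone (camera, adjusted p = 0.394), with the methyltransferase gene EZH2 lower (−0.81 ± 0.17) and CBX6 higher (1.75 ± 0.36). EZH2 stood at −1.17 and CBX6 at 2.34 without the library labelled knockout replicate 2, and at −0.54 and 0.77 without knockout replicate 1. The list gave 5 and 4 without that library, the same counts adjusted over the list alone (camera, adjusted p = 0.935). DNA methylation genes gave 3 and 3 of 21, the same counts adjusted over the list alone (camera, adjusted p = 0.787). These were 4 and 4 without that library (5 and 6 adjusted over the list alone; camera, adjusted p = 0.357). Of 26 BAF and PBAF subunit genes none passed edgeR as named, over all genes or adjusted over the list alone (camera, adjusted p = 0.153), and 4 fell without that library (3 adjusted over the list alone; camera, adjusted p = 0.473). Of the 39 lists with enough members tested, 20 passed camera as named and 24 without that library; 9 and 6 held with an estimated correlation.

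Under CRISPRi against ARID1A, FN1 and SPOCK3 rose and the immediate early genes ARC, EGR2 and FOSB fell in the fit without the library labelled knockout replicate 2, which is in neither group of this comparison but shares in the estimate of the spread. FN1 stood at 1234 ± 27.2 CPM in the sgRNA1 libraries (SD, n = 2) and 20.9 CPM in the vector (n = 1), and SPOCK3 was at least 170.73-fold higher. CLDN18, a tight junction gene of gastric epithelium, stood at 1302.8 against 201.22 CPM. ARC, EGR2 and FOSB fell by 3.15 ± 0.21, 3.04 ± 0.26 and 2.18 ± 0.19 on the log2 scale. Of the 35 AP-1 and immediate early genes 4 rose and 18 fell (4 and 21 adjusted over the list alone; camera, adjusted p = 5.0e-12, and adjusted p = 0.103 with an estimated correlation). In the vector 32 of the 35 were higher than in wild type. ARID1A fell by 1.24 ± 0.12 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 3.3e-06; the alternatives ran from 1.3e-38 to 1).

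With the library labelled knockout replicate 2 in its named group, no gene passed edgeR with Benjamini-Hochberg adjustment for CRISPRi. In that fit 1420 genes had an unadjusted p under 0.05, DESeq2 called 95 higher and 70 lower, limma-voom called none, and ARID1A stood at −1.24 ± 0.56 (edgeR, adjusted p = 0.679). Without that library 874 of 18913 genes rose and 778 fell, of which 311 and 332 changed at least 2-fold; protein-coding genes alone gave 814 and 737. The vector group is 1 library in both fits and is assumed to vary like the groups with replicates, so the vector's own spread was not measured. The common dispersion was 0.0635 with that library and 0.0115 without it. PHLDB2 and PLEKHH2 rose by 5.01 ± 0.41 and 3.97 ± 0.24. METTL7A, KRT17 and FAM189A2 fell by 3.03 ± 0.21, 2.16 ± 0.17 and 2.47 ± 0.15. ZIM3 was at least 145-fold higher in the sgRNA1 libraries and ZNF10 lower by a ratio of 794.45 (95% counting interval 141.72 to 31462), so the sgRNA1 and vector libraries carry different construct transcripts. All 27 genes named for this comparison besides ARID1A passed without that library, with a largest adjusted p of 0.0076 in edgeR, and none passed as named, where the largest was 0.845 in edgeR; the alternatives ran up to 1.

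Interferon response and NRF2 genes were higher as lists under CRISPRi. In the fit without the library labelled knockout replicate 2 these were the lists that held with an estimated correlation, and as named no list held. Without the library labelled knockout replicate 2, 23 of 52 interferon response genes rose and 1 fell (31 and 1 adjusted over the list alone), with a median of 0.64 (camera, adjusted p = 3.9e-15, and adjusted p = 0.013 with an estimated correlation). OAS2 stood at 45.1 ± 1.17 CPM against 11.2, and IFITM3, an interferon-induced membrane protein gene, and OASL rose by 1.18 ± 0.14 and 1.66 ± 0.28. SAMD9 (−0.90 ± 0.20), the member that fell, was named after its values were seen. As named the same list had no member called by edgeR over all genes and 1 adjusted over the list alone (camera, adjusted p = 1.8e-09, and adjusted p = 0.364 with an estimated correlation). NRF2 and glutathione genes gave 12 higher and none lower of 33 (21 and 0 adjusted over the list alone; camera, adjusted p = 2.2e-15, and adjusted p = 0.013 with an estimated correlation), among them AKR1C1 (1.01 ± 0.13), SLC7A11 (1.05 ± 0.13) and AKR1B10 (0.85 ± 0.11). As named the NRF2 list had 1 member called adjusted over the list alone (camera, adjusted p = 1.5e-10, and adjusted p = 0.313 with an estimated correlation).

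Other lists passed camera under CRISPRi but not with an estimated correlation, all values being without the library labelled knockout replicate 2. MHC class I genes gave 10 higher and none lower of 28 (13 and 1 adjusted over the list alone; camera, adjusted p = 1.4e-06, and adjusted p = 0.130 with an estimated correlation), with HLA-B at 0.70 ± 0.13. The AP-1 and immediate early genes were among these lists, with NR4A1 at −1.42 ± 0.13. Unfolded protein and integrated stress response genes gave 13 and 2 of 36 (16 and 2 adjusted over the list alone; camera, adjusted p = 1.2e-06, and adjusted p = 0.131 with an estimated correlation), with HSPA5 at 0.82 ± 0.13. Cholesterol synthesis and SREBP2 genes gave none higher and 4 lower of 27 (1 and 7 adjusted over the list alone; camera, adjusted p = 0.00010, and adjusted p = 0.103 with an estimated correlation), among them INSIG1 (−0.71 ± 0.11). Wnt target genes gave 1 and 8 of 38 (2 and 9 adjusted over the list alone; camera, adjusted p = 0.0016, and adjusted p = 0.131 with an estimated correlation). LGR5, an R-spondin receptor gene, fell by 1.51 ± 0.18, whereas CEMIP, a hyaluronidase gene, rose by 2.44 ± 0.22. ERV-derived genes gave none higher and 5 lower of 27, the same counts adjusted over the list alone (camera, adjusted p = 0.010, and adjusted p = 0.131 with an estimated correlation), with ERV3-1 at 44.2 ± 2.28 against 148.08 CPM. Of 40 genes that silence transposable elements 3 rose and none fell, the same counts adjusted over the list alone (camera, adjusted p = 0.984). Polycomb genes gave none higher and 4 lower of 28 (1 and 4 adjusted over the list alone; camera, adjusted p = 0.385). No DNA methylation gene passed edgeR, over all genes or adjusted over the list alone (camera, adjusted p = 0.828). Of 39 lists 19 passed camera without that library and 13 as named.

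The genes called in both ways of lowering ARID1A moved mostly in the same direction when the library labelled knockout replicate 2 was left out. SPOCK3 stood at log2 fold changes of 12.10 in knockout replicate 1 and 11.83 under CRISPRi, FN1 at 8.37 and 5.88, PHLDB2 at 6.97 and 5.01, and the calcium-binding protein gene CABP1 at 5.17 and 4.69. SPOCK3 had no counts in either control, so its fitted values depend on the prior count. In all 737 genes were higher in both, where independent calls would give 170.15, and 571 lower in both, where they would give 145.87 (1-sided hypergeometric log10 p of −398.97 and −254.18 across genes, which are not independent replicates). The 1308 genes made up 79.2% of the CRISPRi calls, and 48 genes were called in opposite directions. Across the 11718 genes with a mean of at least 5 CPM the log2 fold changes correlated with Pearson r = 0.638 and Spearman rho = 0.596, and across all 18913 with r = 0.376 and rho = 0.441. The comparisons have separate controls. As named there was no overlap to test, since CRISPRi had no calls.

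**Figure D3:**
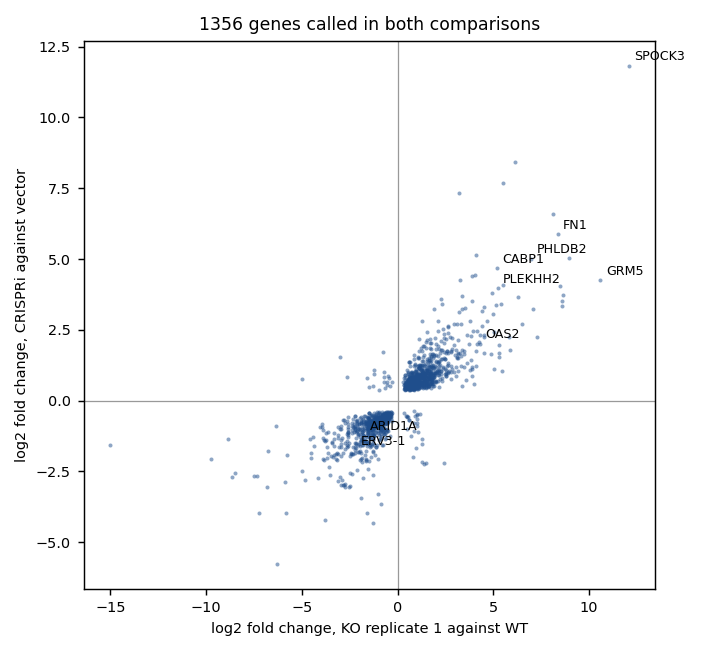
Each point is a gene called in both comparisons, with the log2 fold change of knockout replicate 1 against wild type on the x axis and of CRISPRi against vector on the y axis. Of these genes 1308 lie in the quadrants of equal direction and 48 in the others; ARID1A is labelled among those lower in both.

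The knockout and CRISPRi effects differed for SPP1, CEBPB and MAFF in both fits. SPP1, which encodes osteopontin, stood at 2.19 ± 0.47 CPM in wild type (SD, n = 4) and 26.6 in knockout replicate 1, but also at 35.7 in the vector and 31.5 ± 2.73 in sgRNA1 (SD, n = 2). The difference of effects was 3.91 ± 0.33 as named (edgeR, Benjamini-Hochberg adjusted p = 0.0156). CEBPB, a transcription factor gene of acute phase and fat cell programmes, differed by 2.18 ± 0.21 (edgeR, adjusted p = 0.0248) and MAFF, a small MAF factor gene, by 2.16 ± 0.22 (edgeR, adjusted p = 0.0250). Their vector levels, 89.1 and 86.1 CPM, also lay above their wild-type means of 24.7 and 19.4. These as-named calls were lost without wild-type replicate 2, 3 or 4, without either sgRNA1 library and with the replicate number as a block, and those of CEBPB and MAFF also without wild-type replicate 1, while the differences stayed between 3.76 and 4.06, 2.04 and 2.28, and 2.08 and 2.24 over the libraries left out. They were the only 3 genes past the threshold as named, against 945 higher and 761 lower without the library labelled knockout replicate 2. In that fit BCAT1 and KRT16, a stress keratin gene, rose further in knockout replicate 1 than under CRISPRi, by 9.86 ± 1.02 and 6.32 ± 0.70, and MYBPC1 and IGSF9 fell further, by −13.48 and −7.70, values that depend on the prior count because knockout replicate 1 had no counts of either.

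The vector and wild-type controls of NUGC4 differed from each other. As named 1480 genes were higher and 1034 lower in the vector than in wild type, and 4441 and 3914 without the library labelled knockout replicate 2 (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment), again with 1 vector library assumed to vary like the other groups. Replication-dependent histone genes were lower in the vector. All 39 were called lower without the library labelled knockout replicate 2, over all genes and adjusted over the list alone (camera, adjusted p = 1.2e-21, and adjusted p = 0.082 with an estimated correlation). As named 2 of the 39 were lower (38 adjusted over the list alone; camera, adjusted p = 2.2e-06, and adjusted p = 0.520 with an estimated correlation). In the fit without that library, the RNase P RNA gene RPPH1 stood at −12.77 ± 0.40 and the RNase MRP RNA gene RMRP at −12.08 ± 0.54, the telomerase RNA gene TERC was at least 377.6-fold lower and the histone gene H2BC10 at least 245.87-fold lower. Immediate early genes went the other way, with 32 of 35 AP-1 list members higher and none lower (32 and 2 adjusted over the list alone; camera, adjusted p = 1.9e-27, and adjusted p = 0.059 with an estimated correlation) and ARC higher by 5.25 ± 0.20. CPLX2, a synaptic vesicle gene, was higher by 5.63 ± 0.30, the nucleoside transporter gene SLC28A2 at least 73.0-fold higher, and ZNF10 higher by a ratio of 333.12 (95% counting interval 113.11 to 1622.7). As named these 4 higher genes passed and the 4 lower ones did not, and the 4 calls were lost without any single wild-type or sgRNA1 library.

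In HepG2, CTNNB1 (chromosome 3, 41199505 to 41240443, GRCh38.p14) rose from 382.04 ± 3.71 to 1544.7 ± 9.51 CPM (SD, n = 2 each). The fitted change, with TMM factors, was 4.06-fold (log2 fold change 2.02 ± 0.06 SE, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 1.2e-18). Counts per gene cannot separate the transgene from the endogenous copies, of which HepG2 is known to carry an activated one. Of the genes made by hepatocytes, PLG, the plasminogen gene, rose from 12.9 ± 0.40 to 66.3 ± 4.09 CPM, FGB, a fibrinogen gene, from 207.23 ± 10.7 to 627.96 ± 69.9, and CYP7A1, the rate-limiting enzyme gene of bile acid synthesis, rose by 2.31 ± 0.24. The metallothionein genes MT1G and MT2A fell by 5.46 ± 0.22 and 2.67 ± 0.08. ARID1A changed by −0.01 in these cells.

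Of 15703 genes 2014 rose and 1790 fell in HepG2 with the CTNNB1 transgene (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment), of which 179 and 250 changed at least 2-fold. Without HepG2 vector replicate 1 the counts were 1212 and 1191, and DESeq2's Wald test gave 1121 and 1071. Further large gains were BAAT (1.66 ± 0.13), which encodes the enzyme that conjugates bile acids, the glucuronosyltransferase gene UGT2B4 (2.83-fold) and AKR1C4 (1.47 ± 0.12). Further large losses were MT1E (−3.27 ± 0.13), MT1F (−2.39 ± 0.19), the fucosyltransferase gene FUT1 (−2.89), IGFBP7 (−2.52), the Notch target HEY1 (−2.66 ± 0.10) and ASNS (−2.67 ± 0.10), the asparagine synthetase gene, whose reads can be shared with a read-through gene, so that its counts are uncertain. All 44 genes named for this comparison but AXIN2 passed the test.

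**Figure D4:**
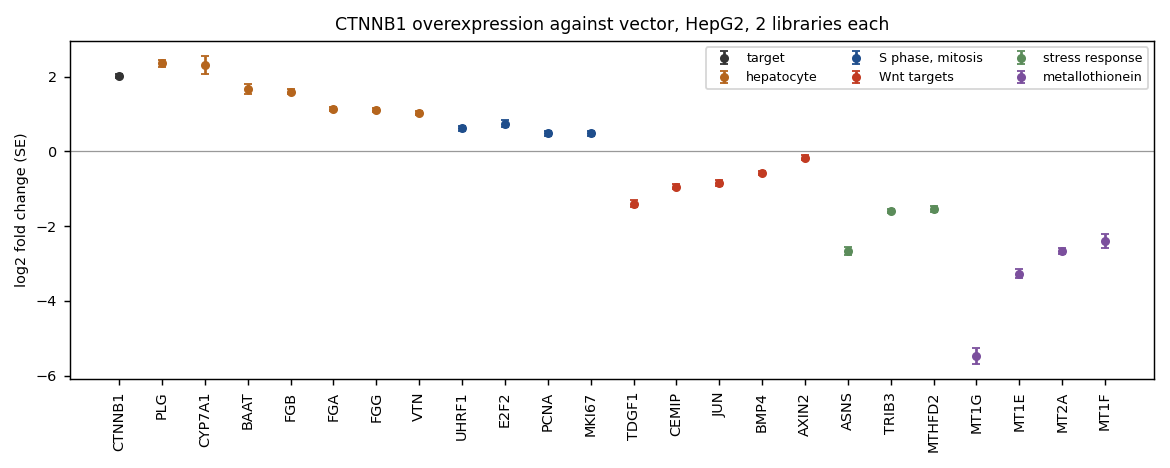
Points give the log2 fold change of CTNNB1 overexpression against vector in HepG2 for 24 genes, with bars of 1 standard error (2 libraries per group). PLG, CYP7A1 and the fibrinogen genes lie above 0, and the metallothionein genes, ASNS, TRIB3 and MTHFD2 lie below it.

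Hepatocyte identity genes gave 25 higher and 1 lower of 44 (26 and 1 adjusted over the list alone), with a median log2 fold change of 0.32 (camera, adjusted p = 1.6e-12, and adjusted p = 0.269 with an estimated correlation). FGA, FGG and VTN rose by 1.14 ± 0.06, 1.11 ± 0.07 and 1.03 ± 0.06. Genes of perivenous hepatocytes, the liver zone in which beta-catenin is active, gave 9 higher and 5 lower of 20 (9 and 6 adjusted over the list alone; camera, adjusted p = 0.850). Wnt and beta-catenin target genes gave 1 higher and 14 lower of 30 (1 and 16 adjusted over the list alone), with a median of −0.20 (camera, adjusted p = 7.6e-06, and adjusted p = 0.269 with an estimated correlation). Those that fell included TDGF1 (−1.40 ± 0.10), which encodes a Nodal coreceptor, CEMIP (−0.94 ± 0.07), JUN (−0.85 ± 0.09) and BMP4 (−0.58 ± 0.06). AXIN2, a widely used readout of beta-catenin signalling, was named after its values were seen and stood at 93.4 ± 6.46 against 105.7 ± 7.11 CPM (SD, n = 2 each), a log2 fold change of −0.17 ± 0.07 (edgeR, Benjamini-Hochberg adjusted p = 0.0656).

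Proliferation genes rose in the overexpressing cells. Replication and S phase genes gave 32 higher and none lower of 42 (34 and 0 adjusted over the list alone), with a median of 0.36 (camera, adjusted p = 1.7e-15, and adjusted p = 0.269 with an estimated correlation), among them UHRF1 (0.62 ± 0.06), which recruits maintenance DNA methylation, the cell cycle factor gene E2F2 (0.75 ± 0.09) and the replication clamp gene PCNA (0.48 ± 0.06). Mitosis genes gave 17 and 1 of 40 (22 and 2 adjusted over the list alone; camera, adjusted p = 7.6e-06, and adjusted p = 0.424 with an estimated correlation), with MKI67 at 0.48 ± 0.06, and DNA repair genes 22 and none of 45 (25 and 1 adjusted over the list alone; camera, adjusted p = 1.1e-05, and adjusted p = 0.269 with an estimated correlation). Cholesterol synthesis genes gave 15 and 1 of 26 (17 and 1 adjusted over the list alone; camera, adjusted p = 7.6e-06, and adjusted p = 0.328 with an estimated correlation), with HMGCS1 at 1.01 ± 0.07.

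Genes of the unfolded protein and integrated stress response moved both ways. Of the 38 tested 9 rose and 25 fell (9 and 26 adjusted over the list alone), with a median of −0.73 (camera, adjusted p = 6.1e-14, and adjusted p = 0.368 with an estimated correlation). TRIB3, a stress-induced pseudokinase gene, and MTHFD2, a mitochondrial folate enzyme gene, both known targets of ATF4, fell by 1.60 ± 0.06 and 1.53 ± 0.08. ATF4 itself, HSPA5 and MANF were named after their values were seen. ATF4, the transcription factor gene of the integrated stress response, fell from 544.2 ± 10.4 to 290.53 ± 33.0 CPM (SD, n = 2 each), while the chaperone gene HSPA5 rose from 690.51 ± 6.51 to 1107.9 ± 6.32 and MANF, another gene of the endoplasmic reticulum, from 28.2 ± 1.25 to 48.2 ± 1.83. NF-kB targets gave 1 higher and 9 lower of 17 (1 and 10 adjusted over the list alone; camera, adjusted p = 7.6e-06, and adjusted p = 0.269 with an estimated correlation), with the chemokine gene CCL20 at −0.94 ± 0.06 and IER3 at −1.20 ± 0.07. AP-1 genes gave 1 and 13 of 28 (1 and 14 adjusted over the list alone; camera, adjusted p = 6.3e-06, and adjusted p = 0.410 with an estimated correlation). Glycolysis and hypoxia genes gave 5 and 12 of 38 (5 and 16 adjusted over the list alone; camera, adjusted p = 0.0011, and adjusted p = 0.545 with an estimated correlation), with the glucose transporter gene SLC2A1 at −1.40 ± 0.07. Epithelial junction and keratin genes gave 1 and 10 of 26, the same counts adjusted over the list alone (camera, adjusted p = 0.00023, and adjusted p = 0.269 with an estimated correlation), with KRT19 at −1.33 ± 0.08.

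Of 37 genes that silence transposable elements 13 rose and none fell in HepG2 (15 and 1 adjusted over the list alone; camera, adjusted p = 0.00052, and adjusted p = 0.368 with an estimated correlation). Among them was HELLS (0.51 ± 0.07), which encodes a chromatin remodeller needed for DNA methylation of repeats and is also a replication-linked gene. ERV-derived genes gave 2 higher and 2 lower of 21, the same counts adjusted over the list alone (camera, adjusted p = 0.850), with ERV3-1, whose counts are uncertain, at 0.82 ± 0.08. DNA methylation genes gave 5 and 3 of 21 (6 and 3 adjusted over the list alone; camera, adjusted p = 0.099). Interferon response genes gave 9 higher and 3 lower of 35 (9 and 4 adjusted over the list alone; camera, adjusted p = 0.610) and MHC class I genes 2 and 4 of 28, the same counts adjusted over the list alone (camera, adjusted p = 0.399). Immune checkpoint ligand genes gave 4 and 6 of 22 (5 and 6 adjusted over the list alone; camera, adjusted p = 0.820, with a median of 0.04 although the test's direction was down). Chemokine and cytokine genes gave 1 and 5 of 14, the same counts adjusted over the list alone (camera, adjusted p = 0.040, and adjusted p = 0.368 with an estimated correlation). In all 21 of 38 lists passed camera and none held with an estimated correlation, the smallest such adjusted p being 0.269. In simulated data edgeR called all 100 genes changed by a log2 of 1 in this comparison, 37 of 100 for the knockout as named and 5 of 100 for CRISPRi as named, against 90 and 89 of 100 without the library labelled knockout replicate 2.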

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

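The tests of the explanations weighed in this part were chosen, with their bounds, only after the results were seen, whereas the tests of a difference between knockout and CRISPRi effects were planned. The screen of single wild-type libraries was limited to named genes with at least 40 counts over the wild-type group, also chosen after seeing the data.

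The library labelled knockout replicate 2 held ARID1A at 140.59 CPM, the level of the vector. A mislabelled column needs the genes moved by lower ARID1A to lie near the vector there. The 1308 genes that moved alike in knockout replicate 1 and under CRISPRi lay at a median of 0.049 from the vector in their shared direction (quartiles −0.046 to 0.147), against 0.860 in the sgRNA1 libraries, so a wrong label remains a candidate explanation. A knockout clone whose transcript escaped decay needs those genes to have moved, and the upper quartile of 0.147 argues against it. Across expressed genes this library and the vector gave a chi-square per degree of freedom of 2.46. That lies below the 3.52 of the sgRNA1 pair and the 6.07 to 18.6 of wild-type pairs. These values argue against a knockout like that of replicate 1 in this library. Which sample the column holds was not determined; a library of the vector group may be one possibility, since ZNF10 stood at 19.9 CPM there, 23.39 in the vector and at most 0.21 in the other NUGC4 libraries.

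Without the library labelled knockout replicate 2, 47 of 52 interferon response and 21 of 28 MHC class I genes rose in the knockout and 23 and 10 under CRISPRi (1 interferon gene fell in each; camera with an estimated correlation, adjusted p = 0.010 and 0.013 for interferon, 0.052 and 0.130 for MHC class I), and as named CRISPRi had no member called over all genes (1 interferon gene adjusted over the list alone). Of the 52 interferon genes 51 lie on other chromosomes than chromosome 6, which carries the MHC. Extra copies of chromosome 6 therefore cannot directly account for their median of 1.58 in knockout replicate 1 (quartiles 0.94 to 3.18). Whether such a gain raised them indirectly was not tested. Within 28 to 34 Mb of chromosome 6, 11 MHC class I genes had a median of 1.62 and 92 other genes 0.35, a difference that 100000 resamples reached with p = 7.0e-05 (2-sided permutation test across genes), so a gain of the region as the whole cause of the MHC class I rise is argued against too. For CRISPRi the construct and the fall of ARID1A cannot be told apart, because ZIM3, at 27.2 CPM in the sgRNA1 libraries, marks a construct that no control library carries. The knockout side rests on 1 clone, so a trait of that clone stays open, untested.

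The NUGC4 vector library differed from wild type in 8355 genes without the library labelled knockout replicate 2. Capture of RNA without a poly(A) tail in the wild-type libraries may account for the histone genes: 39 of them had a median of −6.33 in the vector against wild type and 0.11 in knockout replicate 1 (quartiles −0.14 to 0.37), which is of the wild-type kind. Among other protein-coding genes 5822 of 13023, or 44.7%, were called. This share cannot decide whether such RNA was the whole cause, since the kind of library may itself move counts of protein-coding genes. For those genes the kind of library, the construct and the culture cannot be told apart, since they change together.

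Of 56 wild-type sets of values screened, 8 had 1 library farther from the others than the limit for 4 samples; chance alone gives such a result in about 1 of 20 sets, and genes of 1 library are not independent. Replicate 3 held 5 of the 8, with ARC at 2.41 CPM (the others 1.35 to 1.43), EZH2 at 113.85 (119.03 to 119.44), LGR5 at 50.3 (64.4 to 66.5), LIF at 58.0 (47.6 to 48.1) and PEG10 at 7.23 (9.50 to 9.55). Replicate 1 held AKR1C1 at 171.76 (146.82 to 149.9) and IFI6 at 8.12 (11.81 to 11.95), and replicate 4 held H2BC10 at 58.1 (38.4 to 41.0).

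Knockout and CRISPRi effects differed by edgeR's test of the difference itself. As named SPP1 differed by 3.91, CEBPB by 2.18 and MAFF by 2.16 on the log2 scale, calls that were lost without wild-type replicate 2, 3 or 4 or either sgRNA1 library. Without the library labelled knockout replicate 2 the same genes differed by 3.76, 2.04 and 2.21, BCAT1 by 9.86, KRT16 by 6.32, MYBPC1 by −13.48 and IGSF9 by −7.70. In that fit the knockout effects on SPP1, CEBPB and MAFF were 3.58, 1.73 and 2.31 and the CRISPRi effects −0.18, −0.31 and 0.10, with the vector itself at 35.7, 89.1 and 86.1 CPM.

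Of the lists, 23 passed camera for the difference as named and 21 without the library labelled knockout replicate 2; those that held with an estimated correlation are given. As named their median differences were 0.39 for MHC class I genes, 0.84 for chemokines and cytokines, 0.91 for NF-kB targets, 0.33 for p53 targets and 0.62 for cholesterol synthesis genes. Without that library they were 0.93 for interferon response genes, 0.92 for chemokines and cytokines, 0.89 for AP-1 genes, 0.84 for NF-kB targets, 0.45 for p53 targets, −0.46 for replication and S phase genes, 0.57 for cholesterol synthesis genes and 0.58 for unfolded protein and integrated stress response genes.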

How the results depend on the processing

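The alternatives were planned, except protein-coding genes alone, the block with all NUGC4 libraries in the fit and the overlap without the library labelled knockout replicate 2, which were chosen after seeing the data; where a value moved, the cause was not tested unless given. CTNNB1 kept its rise in HepG2 under every setting run, 2.00 to 2.03 over the libraries left out. Over the settings of the 122 pairs of a named gene and a comparison, 1248 left direction and call the same, 141 brought a call, 192 ended one and 10 reversed the direction. A pair that was not called as named and stayed so counts as the same, and none of the 27 CRISPRi pairs was called as named.

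With an estimated correlation 9 lists passed for the knockout (20 with the preset one), 0 for CRISPRi (13) and 0 for CTNNB1 (21); camera with the preset correlation is the test that called those, and fry called 6 for CRISPRi. Without the filter on low counts edgeR called 48 genes higher and 48 lower for CRISPRi, 137 for the difference of effects and an overlap of 76. DESeq2's Wald test called 95 and 70 for CRISPRi, 135 for the difference and 1121 and 1071 for CTNNB1. With an absolute log2 fold change of at least 1, 1097 and 1198 remained for the knockout and 179 and 250 for CTNNB1, a stricter threshold by construction. With only the compared groups in the fit, 1690 genes were higher in the knockout, 2184 and 1966 changed under CRISPRi (ARID1A −1.26; edgeR, adjusted p = 1.3e-38, over all settings 1.3e-38 to 1), 7697 differed between vector and wild type and 1206 overlapped; fewer libraries then set the spread. All mapped libraries in 1 fit gave 40 and 77 for CTNNB1, the NUGC4 spread (common dispersion 0.0635 against 0.00197) entering by construction. Protein-coding genes alone gave 1686 higher in the knockout and 1512 between vector and wild type, with fewer genes tested.

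With the replicate number as a block edgeR called 0 genes higher and 0 lower in the knockout, 0 for the difference of effects, and 1532 and 1384 for CTNNB1. For CRISPRi, the vector against wild type and the overlap the block was fitted with all 9 NUGC4 libraries (2 residual degrees of freedom), where edgeR called 0 genes in each and 0 and 0 in the knockout, with 830, 4519 and 4535 genes at an unadjusted p under 0.05 for CRISPRi, the vector and the knockout. Without the library labelled knockout replicate 2 the block (1 residual degree of freedom) gave 2251 and 1698 for CRISPRi, 4429 and 4295 in the knockout, 2149 and 1856 for the difference and 5167 and 4447 for the vector against wild type. The labels tie the numbers to no shared culture, batch or day. Deviations of equally numbered libraries correlated at −0.0816 in HepG2 and at −0.0441 and 0.00897 in the knockout and wild type, which cannot exclude a shared batch, since 2 libraries mirror each other around their mean and the knockout libraries are of 2 kinds. The planned tests of transposable element features were not run, since the rows are genes.

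Directions reversed for TK1 in the knockout with limma-voom (−0.11) and the block (−0.14; −0.079 with all NUGC4 libraries), and for the difference of effects in MYBPC1 with limma-voom (−4.48) and the block (−0.072) and in IGSF9 with limma-voom (−1.62); none of these was called as named. Leaving out single libraries reversed ARID1A in the knockout (0.25 without knockout replicate 1; edgeR, adjusted p = 0.0734, over all settings 1.5e-08 to 0.610), GRM5 (−1.78 without the same library), TK1 (−0.95), and in the difference of effects MYBPC1 (−13.48) and IGSF9 (−7.70), the last 3 without the library labelled knockout replicate 2.

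Over the libraries left out in turn, genes higher in the knockout ran from 1100 to 4563 and lower from 836 to 4412. Without wild-type replicates 1 to 4 they were 1100 and 836, 1139 and 859, 1468 and 1105, and 1493 and 1060. Without knockout replicate 1 they were 4563 and 4412, a comparison of the other kind of library with wild type, without the library labelled knockout replicate 2 3682 and 3546, and without sgRNA1 replicates 1 and 2 1549 and 1223, and 1539 and 1235. CRISPRi calls ran from 0 to 874 higher and 0 to 778 lower, above 0 only without knockout replicate 1 (871 and 775) or without the library labelled knockout replicate 2. The difference of effects ran from 0 to 4694, with 1 without wild-type replicate 1, 0 without any other wild-type or either sgRNA1 library, 4694 without knockout replicate 1 and 1706 without the library labelled knockout replicate 2. Vector against wild type ran from 158 to 8378, with 166, 158, 310 and 459 without wild-type replicates 1 to 4, 8378 and 8355 without knockout replicate 1 and the library labelled knockout replicate 2, and 426 and 427 without sgRNA1 replicates 1 and 2. ARID1A ran from −1.74 to 0.25 in the knockout and from −1.28 to −1.20 under CRISPRi. For CTNNB1, genes higher ran from 1212 to 1942 and lower from 1191 to 1615, the lowest without HepG2 vector replicate 1. Lists ran from 19 to 24 in the knockout, 13 to 19 under CRISPRi and 18 to 21 for CTNNB1, and the overlap was 1308 without the doubted library. Ranges of reversed genes were −0.95 to 0.65 for TK1, −1.78 to 11.39 for GRM5, and for the difference of effects −13.48 to 1.34 for MYBPC1 and −7.70 to 1.68 for IGSF9. In NUGC4 as named, the recovery of simulated 2-fold changes, 37 of 100 in the knockout and 5 of 100 under CRISPRi, limits what counts of 0 can show.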

Other observations

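The tests of the ZNF and metallothionein families and the split of chromosome 15 were chosen only after the results were seen; the list tests were planned.

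Further lists moved in HepG2 with the CTNNB1 transgene. Heat shock genes gave 10 higher and none lower of 18, the same counts adjusted over the list alone (camera, adjusted p = 7.6e-06; adjusted p = 0.269 with an estimated correlation), with HSPA1A, an inducible chaperone gene, at 0.83 ± 0.08. Imprinted genes gave 7 and 2 of 22, the same counts adjusted over the list alone (camera, adjusted p = 0.0012; adjusted p = 0.328 with an estimated correlation), with the fetal growth genes DLK1 and IGF2 at 1.04 ± 0.06 and 0.91 ± 0.06. HOX genes gave none higher and 4 lower of 8, the same counts adjusted over the list alone (camera, adjusted p = 0.00064; adjusted p = 0.269 with an estimated correlation), with HOXD1 at −1.37 ± 0.07. Among perivenous hepatocyte genes the glutamate transporter gene SLC1A2 rose by 0.75 ± 0.07 while the retinal dehydrogenase gene ALDH1A1 fell by 0.64 ± 0.06. The p53 targets gave 15 higher and 3 lower of 31 (16 and 4 adjusted over the list alone; camera, adjusted p = 0.00064; adjusted p = 0.269 with an estimated correlation).

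In NUGC4 without the library labelled knockout replicate 2, cholesterol synthesis genes gave 14 higher and 3 lower of 27 in the knockout (16 and 3 adjusted over the list alone; camera, adjusted p = 0.00079; adjusted p = 0.068 with an estimated correlation), where CRISPRi gave none higher and 4 lower. Cytosolic ribosomal protein genes gave 28 and none of 52 in the knockout (31 and 0 adjusted over the list alone; camera, adjusted p = 8.7e-07; adjusted p = 0.301 with an estimated correlation), and 43 and none in the vector against wild type, where the kind of library, the construct and the culture change together. Mitochondrially encoded genes gave none higher and 10 lower of 12 in knockout replicate 1 (0 and 11 adjusted over the list alone; camera, adjusted p = 0.00019; adjusted p = 0.403 with an estimated correlation). ARID1B, the paralogue of ARID1A, stood at 54.5 ± 1.24 CPM in sgRNA1 (SD, n = 2) against 73.8 in the vector.

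A hypothesis formed from the gene tables was that lower ARID1A lowers zinc finger genes with ZNF symbols as a set. Of 383 such genes 30 rose and 73 fell in knockout replicate 1 (camera, p = 0.127) and 4 rose and 22 fell under CRISPRi (camera, p = 3.5e-05; p = 0.064 with an estimated correlation). The knockout gave p = 0.425 with an estimated correlation. As named 10 rose and 50 fell in the knockout (camera, p = 0.00087, and p = 0.243 with an estimated correlation). None was called under CRISPRi (camera, p = 3.6e-05, and p = 0.162 with an estimated correlation). The bound set for the hypothesis, p under 0.05 in both comparisons with an estimated correlation, was not met, so it was not supported. In knockout replicate 1 the family's median log2 fold change was −0.098, against −0.073 for all genes tested.

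A further hypothesis was that CTNNB1 overexpression lowers the metallothionein family as a set. All 6 members tested fell, with a median log2 fold change of −2.53 (camera, p = 1.9e-13; p = 0.047 with an estimated correlation), in 2 libraries per group. The hypothesis was formed on the same data, in which MT1G, MT1E, MT2A and MT1F were already among the largest falls. These values restate that fall and are no separate test of the hypothesis.

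On chromosome 15, the 98 genes from 75 Mb onward had a median log2 fold change of 0.47 in knockout replicate 1, with 52 higher and 11 lower, against 0.061 for the 224 genes before it and 0.067 for the same 98 genes under CRISPRi. On chromosome 6 the medians over 558 genes were 0.31 and 0.037.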
